A study of Mus musculus with 6 samples.

How the data were processed

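ATAC-seq was measured in 6 samples of HT mouse pancreatic cancer cells, with 2 samples in each of 3 groups (Control, Mcrs1ox and Mcrs1oxYy1KO), grouped by the genotype in the labels. The deposited data used here were 3 narrowPeak lists, and the labels of both samples of a group name the same list. Per the submitters' processing notes, fastp 0.22.0, Bowtie2 2.5.0, MACS2 2.2.7.1, deepTools 3.5.1, bedtools 2.30.0 and the genome build GRCm38 were used, with no role or order stated; how the samples of a group were combined and the MACS2 settings are not given in the sources used here. Column 7 of the deposited lists holds the peak caller's fold enrichment over local background, a linear ratio, and columns 8 and 9 of the deposited lists hold the −log10 p-value and −log10 q-value of each peak. Column 10 of the deposited lists holds the distance of the summit from the start of the peak. The lists hold no read counts, so the depth of the samples is unknown and no count model was used. No other columns of per-sample values were left out (0 columns).

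Peaks on chromosomes 1 to 19, X and Y were kept. This left out 51 Control, 57 Mcrs1ox and 56 knockout peaks on the mitochondrial genome and unplaced sequences. A peak was shared when it overlapped a peak of another list by at least 1 bp, and was otherwise gained or lost. Peaks of all lists that overlapped were merged to a union for the counts of lists that held a region. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Matched shares were computed over peaks of the same decile of fold enrichment, and the floor for a count of 0 was 3 counts. With 1 list per group, differences between groups were described and not tested.

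Gene positions came from a RefSeq table of 49997 genes on GRCm38.p6, of which 21883 protein-coding genes lay on the chromosomes kept. The table gives no strand, exons or sequence. The plan, fixed before the data were examined, asked for peaks within 1 kb of a transcription start site; these became peaks within 1 kb of either annotated end of a protein-coding gene, and such a peak can belong to a neighbouring gene. The planned shares of peaks with a YY1 motif or with other motifs, and the part of the Mcrs1 gene by exon, were not computed for want of a genome sequence and of exons. Distal regions lay farther than 1 kb from any end of a gene of any type.

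Before the data were examined, 15 gene lists were fixed: MHC class I antigen presentation, MHC class II and co-stimulation, interferon response, chemokines and cytokines, NF-kB signalling, INO80 and NSL complexes, cytosolic ribosomal proteins, oxidative phosphorylation, ductal and epithelial markers, mesenchymal markers, acinar and endocrine markers, immune cell markers, endothelial markers, housekeeping promoters, and proliferation and oncogenic drivers. Of their 347 entries 3 had no match (Mx1, Mx2 and Cxcl11), and Tmem173 was matched as Sting1. For each list, regions gained minus regions lost within 50 kb of either end of a member were summed and ranked among 10000 random gene lists of the same size, matched on the decile of the number of regions within 50 kb. The percentile describes these lists and is not a test.

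The rule for named genes was fixed then too. It took, for each comparison and direction, up to 10 members of the gene lists and 10 protein-coding genes of the genome, without predicted symbols, that had an end peak in 1 list and no peak within 1 kb in the other, with the largest fold enrichment. It also took 5 distal regions per direction, 5 regions held by Mcrs1ox alone, 5 missing from Mcrs1ox alone, and always Mcrs1, Yy1, B2m, H2-K1, H2-D1, Tap1, Tap2, Tapbp, Nlrc5, Psmb8, Psmb9 and Cd274. Because a peak of the other list can overlap the same peak just beyond 1 kb, the genes of the genome were also named with no such overlap, a rule chosen after seeing the data.

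Alternatives fixed before the data were examined were a −log10 q of at least 5, lists of equal length (the length of the shortest list, or the 30000 peaks with the largest −log10 p), presence among the 20000 strongest peaks with absence from the other full list, an overlap of 50% of both peaks, the summit of a peak inside the other peak, autosomes only, gene-end windows of 500 and 2500 bp, and link windows of 20 and 100 kb. With lists of equal length, a peak of the other list below the cut counted as absent, so a gain or loss there can be a change of rank only. Overlap code was tested on simulated data made from the Control list of 91800 peaks, and percentile code on simulated values for made-up genes. All 2000 planted losses and all 1500 planted gains of a simulated Mcrs1ox list were recovered. Shared peaks were moved little and gains were planted away from other peaks, so this checks the code and not the calling of weak peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.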

Results

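Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in HT cells, a mouse pancreatic cancer cell line. The 6 samples formed 3 conditions with 2 samples each. Control cells carried a control guide RNA. Mcrs1ox cells overexpressed Mcrs1 and carried the control guide, and the knockout cells (Mcrs1oxYy1KO) overexpressed Mcrs1 and carried a guide against Yy1. Mcrs1 encodes a subunit of the INO80 chromatin remodelling complex and of the NSL histone acetyltransferase complex, and Yy1 encodes a zinc finger transcription factor that associates with INO80. Each condition had 1 peak list that stood for both of its samples, so no difference had a replicate check and none was tested between conditions. On chromosomes 1 to 19, X and Y the lists held 91800 peaks in Control, 91110 in Mcrs1ox and 94760 in the knockout, which covered 41.8, 41.3 and 42.4 Mb. Median fold enrichment was 7.16 in Control, 6.72 in Mcrs1ox and 6.86 in the knockout, and median peak width was 436, 417 and 414 bp. Fold enrichment of a peak was the authors' own value and was used to rank and describe peaks within a list. Values given side by side were each read from their own list. Read depth was unknown, and all intervals are exact 95% binomial intervals that cover counting error only.

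The targeted genes were examined first. Both genes had a peak at an annotated end in all 3 lists. The main Yy1 peak lay at its lower end, on chromosome 12 at 108792651 to 108793262 in Control, with fold enrichment 7.41 in Control, 7.94 in Mcrs1ox and 7.18 in the knockout. A small guide-directed lesion leaves no mark in a peak list, so this peak checks neither the knockout nor its label. The main Mcrs1 peak lay at its upper end, on chromosome 15 at 99251724 to 99252670 in Control, with fold enrichment 7.94, 7.52 and 7.21 in the same order. Within 5 kb of Mcrs1 there were 2 peaks in Control and 5 in each of the other lists, and no Mcrs1 peak lay inside the gene body away from its ends in any list. In both other lists 2 peaks covered the span of the main Control peak, and another weak peak had fold 3.04. A further peak below the gene, which overlapped no Control peak, had fold 4.99 in Mcrs1ox and 5.62 in the knockout. The count of peaks thus reflects in part how the peak caller split them.

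The next comparison asked which regions differed in accessibility between Mcrs1ox and Control cells. Mcrs1ox cells had a gene-end peak that Control lacked at Oas2 (fold 8.10) and Gbp7 (8.0), which encode interferon-induced antiviral proteins, and at H2-Ab1 (6.63), which encodes a class II major histocompatibility complex (MHC) chain. Control had a gene-end peak that Mcrs1ox lacked at Twist2 (7.91), a transcription factor of mesenchymal cells, at the oncogene Mycn (7.66), and at Oasl2 (5.48) and Sting1 (4.69), genes of antiviral signalling. Over the whole genome, 20150 of 91110 Mcrs1ox peaks overlapped no Control peak (22.1%, interval 21.9 to 22.4), and 20635 of 91800 Control peaks overlapped no Mcrs1ox peak (22.5%, interval 22.2 to 22.8). The peaks found in 1 of these lists were weaker and narrower: Control peaks missing from Mcrs1ox had median fold 5.61 and width 196 bp, against 7.97 and 491 bp for those that were shared. Of the Control peaks in the top decile of fold enrichment, 322 of 9180 were missing from Mcrs1ox (3.51%), against 3648 of 9180 in the second decile (39.7%). In the reverse direction the top decile of Mcrs1ox held 114 of 9111 peaks missing from Control (1.25%).

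**Figure D1:**
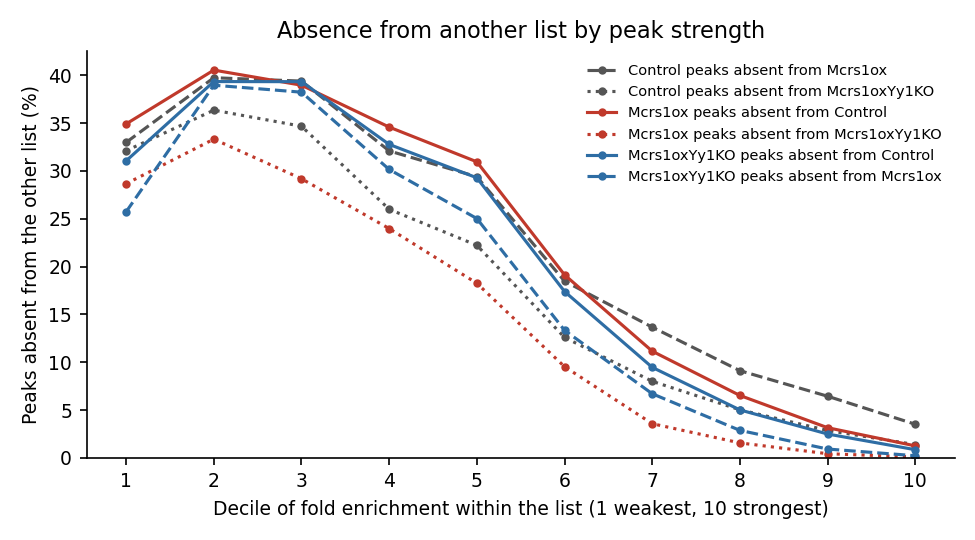
Percent of the peaks of a list that overlapped no peak of another list (y axis, from 0), by decile of fold enrichment within the list (x axis, weakest to strongest), with a line for each ordered pair of lists, coloured by the list and styled by the list the peaks were absent from. Peaks of the top decile were absent in 3.51% (Control peaks missing from Mcrs1ox) to 0.09% (Mcrs1ox peaks missing from the knockout list) of cases.

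Of the fixed gene lists, 10 members gained an end peak in Mcrs1ox against Control and 10 lost it. The other gained members were Cdh5 (6.04, the endothelial cadherin), Ptprc (5.68, the leukocyte marker CD45), Il1a (5.21) and Il33 (4.62), both cytokines, Cd4 (4.49), Sox17 (3.83) and Cox5a (3.0, a subunit of cytochrome c oxidase). The other lost members included Thy1 (5.48), Gbp5 (4.17), Cldn4 (3.78, a tight junction protein), Ccl2 (3.41, a monocyte chemoattractant) and Bcl3 (2.56, a cofactor of NF-kB). Among the 30000 strongest peaks of each list, of these 20 differences that at Mycn remained, and with only the 20000 strongest peaks called present none did.

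Among all protein-coding genes, the strongest gained end peaks that no Control peak touched lay at Zfp819 (15.5) and Zfp709 (13.2), which encode zinc finger proteins. They were followed by Gatm (12.96), which encodes an enzyme of creatine synthesis, Pm20d1 (12.1), Izumo1 (12.0) and Zfp616 (11.8). A peak shared by Klhl10 and Nt5c3b (11.8) and another shared by Rbak and Spdye4b (11.3) followed. The strongest lost end peaks lay at Serpinb9f (17.7), Zfp474 (16.95), Map9 (16.4) and Serpinb9d (16.0). Serpinb9f and Serpinb9d are members of a protease inhibitor cluster on chromosome 13. Next came Lect2 (15.5), Hs3st3b1 (15.2) and Chst7 (14.5), the last pair being sulfotransferases of glycosaminoglycans. Olfr136 (14.3), Naa60 (14.3) and Kprp (14.1) completed these. In total 483 of 21883 protein-coding genes had an end peak in Mcrs1ox only and 496 in Control only, while 11667 had one in both lists. The balance moved when each list was cut to its 30000 strongest peaks, where 743 genes gained an end peak and 312 lost it. At that cut a weaker peak of the other list counts as absent, so the 743 include genes with an end peak in both full lists. Peaks among the 20000 strongest against full lists gave 17 and 25. The 17 include Zfp369 and Myo5a, whose end peaks overlapped a Control peak beyond 1 kb. The requirement that no peak of the other list overlap beyond 1 kb was chosen after seeing the data and left 459 and 470 genes. Without it Dync2h1, Zfp369 and Myo5a stood among the 10 strongest gained genes and Vstm2l among the lost.

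Away from gene ends, the strongest gained regions lay 42520 bp from Olfr761 on chromosome 17 (37995542 to 37996181, fold 17.9) and 17369 bp from Hes1, a repressor of the Notch pathway, on chromosome 16 (30047329 to 30047988, 16.1). Others lay inside Ptprm on chromosome 17 (67150241 to 67150958, 15.8), inside Trappc9 on chromosome 15 (72630629 to 72630862, 15.8) and 166249 bp from Lacc1 on chromosome 14 (76854845 to 76855490, 15.4). The strongest lost regions lay 129046 bp from Dusp6, a phosphatase of ERK kinases, on chromosome 10 (99396535 to 99397182, 19.3) and inside Dpysl3 on chromosome 18 (43411019 to 43411598, 19.1). Others lay 258975 bp from Magi1 on chromosome 6 (93415919 to 93416478, 18.9), 9254 bp from Thbs1, a matrix glycoprotein, on chromosome 2 (118102109 to 118102622, 18.5) and inside Ldlrad4 on chromosome 18 (68015632 to 68016258, 18.3). All coordinates are from GRCm38, and a distal region outside any gene is named by the nearest protein-coding gene.

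Changed peaks were mostly distal. Of the gained peaks 9.49% lay within 1 kb of an end of a protein-coding gene (interval 9.09 to 9.91), against 17.8% of all Mcrs1ox peaks and 18.9% of other Mcrs1ox peaks of matched fold enrichment. Of the lost peaks 6.97% did (interval 6.62 to 7.32), against 17.4% of all Control peaks and 19.9% of matched ones. The match did not cover width or −log10 q, and gained peaks had a median width of 180 bp against 483 bp for shared ones. The matched shares thus do not separate position from how readily a peak is called. With each list cut to its 30000 strongest peaks the gained share was 17.4% and the lost share 7.41%. The share of all peaks at that cut was not computed, so these values cannot be set against the shares of all peaks above.

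The genes of MHC class I antigen presentation were described together. Of the 25 members, 23 had an end peak in every list, and H2-Q6 and H2-Q7, whose reads near-identical copies can share, had none. The end peak of B2m, the invariant class I chain, had fold 11.1 in Control, 10.9 in Mcrs1ox and 10.98 in the knockout. Values in the same order were 9.17, 7.97 and 9.05 at H2-K1, 8.44, 7.50 and 6.89 at H2-D1, and 7.07, 6.02 and 6.67 at Tap2. They were 10.8, 8.09 and 9.44 at the stronger end of Tapbp, and 13.7, 14.8 and 13.6 at Cd274, which encodes the ligand PD-L1. The peak between the divergent genes Psmb9 and Tap1, a proteasome subunit and a peptide transporter, had fold 12.3, 11.8 and 11.2. The peak at the other end of Tap1, next to Psmb8, had fold 4.48 in Control, 10.95 in Mcrs1ox and 12.3 in the knockout, so that its ratio to the first peak of the same list was 0.36, 0.93 and 1.1. Nlrc5, the transactivator of class I genes, had a peak at its lower end in Mcrs1ox alone (chromosome 8, 94434156 to 94434402, 5.68) and one near its upper end in all lists. A weak peak above the gene (3.86) was in Mcrs1ox alone too. Inside the gene, Mcrs1ox lacked Control peaks from 94436951 (7.96) and 94458542 (7.22). The knockout had peaks at both places, of fold up to 9.82 and 5.08. Within 5 kb of Nlrc5 there were 7, 6 and 9 peaks in the same order of lists.

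**Figure D2:**
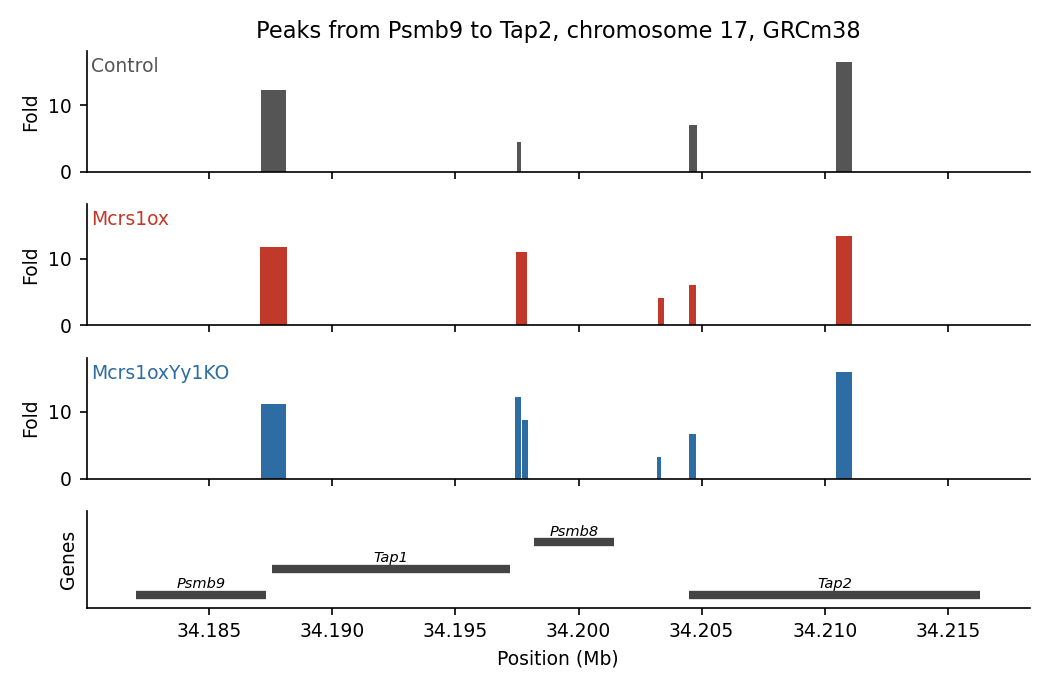
Peaks of each list across Psmb9, Tap1, Psmb8 and Tap2 on chromosome 17 (x axis, position in Mb, GRCm38; y axis, fold enrichment of the peak in its own list, from 0), with the genes drawn to scale. The peak between Tap1 and Psmb8 had fold 4.48 in Control, 10.95 in Mcrs1ox and 12.3 in the knockout list.

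Within 50 kb of the class I genes, 64 region and gene pairs were gained and 29 lost in Mcrs1ox against Control, from 49 and 26 distinct regions, since many of these genes are neighbours. The difference of 35 lay at percentile 96.5 of 10000 random lists, inside their central 95%, and at percentile 79.0 with at most 1 member per 100 kb. It lay outside at a −log10 q of 5 (percentile 99), at the length of the shortest list (98.1) and with links of 100 kb (98.2). The INO80 and NSL complexes lay at percentile 99.3 (63 gained, 24 lost), the endothelial markers at 98.6 (30 gained, 11 lost) and the mesenchymal markers at 1.0 (29 gained, 45 lost), the last with end peaks lost at Twist2 and Thy1. With each list cut to its 30000 strongest peaks these percentiles were 46.6, 4.4 and 4.3, so the endothelial markers turned and the complexes lay near the middle. At that cut a region can count as changed because the other list held it as a weaker peak. The other 12 lists lay between percentile 3.9 (chemokines and cytokines) and 96.5. Over all 3 comparisons 6 of 45 percentiles fell outside the central 95%, against 2.25 expected at that share, and each of the 6 fell inside it under some alternatives.

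End peaks of the other lists differed by few members, with counts given for Control, Mcrs1ox and the knockout in that order. There were 9, 10 and 11 of 15 genes of MHC class II and co-stimulation, 31, 30 and 32 of 37 interferon response genes, 19, 20 and 20 of 27 chemokines and cytokines, and 15, 14 and 14 of 18 NF-kB genes. All 22 genes of the INO80 and NSL complexes and the same 28 of 29 ribosomal protein genes had an end peak in every list. Oxidative phosphorylation had 24, 25 and 24 of 26, housekeeping genes 19, 18 and 18 of 20, and proliferation and oncogenic drivers 27, 26 and 26 of 29. Among cell type markers, ductal and epithelial genes had 18, 17 and 18 of 24, mesenchymal genes 13, 11 and 11 of 22, acinar and endocrine genes 2, 2 and 2 of 18, immune cell genes 4, 6 and 5 of 22, and endothelial genes 1, 3 and 4 of 10.

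The next comparison asked what changed when Yy1 was targeted in Mcrs1ox cells. The knockout list had an end peak that Mcrs1ox lacked at Oasl2 (8.23), Gbp5 (4.13), Cldn4 (4.21), Cd40 (4.85), a co-stimulatory receptor, and the cytokine gene Tnf (3.93), of which the first 3 also had a Control peak. It lacked the Mcrs1ox end peaks at Ptprc, Il1a and Cox5a, which Control lacked as well. An end peak at Tie1 (6.56) overlapped a Mcrs1ox peak farther than 1 kb from the gene. Genome-wide, 17258 of 94760 knockout peaks overlapped no Mcrs1ox peak (18.2%, interval 17.97 to 18.46) and 13535 of 91110 Mcrs1ox peaks overlapped no knockout peak (14.9%, interval 14.6 to 15.1).

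Gained end peaks without any overlapping Mcrs1ox peak were strongest at Zfp474 (9.68), Kcnh1 (9.22), Tas2r126 (8.91), Cytip (8.72), Slc7a12 (8.72), Rgs20 (8.65), Mrgprd (8.53), Dnah3 (8.23), Kprp (8.23) and Lect2 (8.23), and all 10 genes also had an end peak in Control. Lost end peaks were strongest at Slc47a1 (11.1), Cdx1 (9.50, an intestinal homeobox factor), Mdga1 (9.0) and Mup20 (8.91), followed by a peak shared by H2ac1 and H2bc1 (8.53), one shared by Ppfibp1 and Rep15 (8.53), Bcl2l1 (8.04, an inhibitor of apoptosis) and Tmc2 (7.73). Without that requirement, 9 of the 10 strongest gained and 8 of the 10 strongest lost genes had an overlapping peak just beyond 1 kb. Among the 30000 strongest peaks of each list, 8 of these 10 gained and 8 of these 10 lost genes kept their difference. None of the genes named above without an overlapping peak, and none of the list members named for this comparison, did. In total 327 genes gained an end peak and 263 lost it, or 299 and 240 with the requirement. This balance turned when each list was cut to its 30000 strongest peaks, where 251 genes gained an end peak and 484 lost it. Weaker peaks of the other list count as absent there, so the 484 include genes with an end peak in both full lists. With the 20000 strongest against full lists the counts were 7 and 8. Each of those strong peaks overlapped a peak of the other list, so these genes differed only by the 1 kb limit.

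The strongest distal regions gained in the knockout lay 39072 bp from Atxn7l3b on chromosome 10 (112968098 to 112968556, 16.1), 171635 bp from Ccer1 on chromosome 10 (97866561 to 97866871, 15.5) and 190677 bp from Cog6 on chromosome 3 (52791074 to 52791446, 14.4). Others lay 55752 bp from Hdac2 on chromosome 10 (36918018 to 36918545, 14.2) and 2727 bp from Olfr456 on chromosome 6 (42489941 to 42490299, 14.04). Those lost lay inside Fkbp9 on chromosome 6 (56860240 to 56860787, 15.5) and 13126 bp from Olfr974 on chromosome 9 (39928405 to 39928933, 15.2). Others lay inside Wwp2 on chromosome 8 (107519817 to 107520288, 13.7), Epb41 on chromosome 4 (131939330 to 131939936, 13.1) and Rabgap1l on chromosome 1 (160635928 to 160636410, 13). None of these 10 regions was among the 20000 strongest peaks of its list by −log10 p.

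Of the gained knockout peaks 7.43% lay within 1 kb of a gene end (interval 7.04 to 7.83), and of the lost ones 9.07% (interval 8.59 to 9.57). Around the ductal and epithelial markers 32 region and gene pairs were gained and 58 lost, at percentile 0.9, and around the endothelial markers 12 were gained and 22 lost, at percentile 2.4. Both turned when each list was cut to its 30000 strongest peaks, to percentiles 83.5 and 69.4, where weaker peaks of the other list count as absent. The other 13 lists lay between percentile 2.7 (INO80 and NSL complexes) and 96.3 (housekeeping genes), with MHC class I at 45.8 (34 gained, 35 lost). The 20000 strongest Mcrs1ox peaks all overlapped a knockout peak, and the 20000 strongest knockout peaks all overlapped a Mcrs1ox peak, which allows a share of up to 0.015% in each direction at 3 counts, or 0.018% by the exact interval. Every region named for this comparison that had no overlapping peak in the other list thus ranked below these 20000 peaks.

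The study's design then asks whether regions that differed in Mcrs1ox cells returned to the Control state when Yy1 was targeted. Named gained genes mostly kept their peak: Oas2 (6.36), Gbp7 (6.95), H2-Ab1 (6.34), Cdh5 (5.72), Il33 (5.33), Cd4 (4.34) and Sox17 (3.99) had an end peak in the knockout list too. So did Zfp819 (12.7), Zfp709 (13.2), Gatm (14.1), Pm20d1 (10.4), Izumo1 (9.82) and Zfp616 (8.23). Of the lost genes, Zfp474, Lect2, Kprp, Olfr136 (7.75), Serpinb9d (5.81) and Serpinb9f (5.33) had a peak again in the knockout. No knockout peak stood at Map9, Hs3st3b1, Chst7, Naa60, Twist2, Mycn, Thy1, Sting1, Ccl2 or Bcl3. The 5 strongest Control regions that were missing from Mcrs1ox and present in the knockout were those named above near Dusp6, Dpysl3, Magi1, Thbs1 and Ldlrad4. The 5 strongest Mcrs1ox regions missing from both other lists included those named above for Olfr974, Epb41 and Rabgap1l. The others lay 609190 bp from Cntn5 (chromosome 9, 11513965 to 11514201, 12.8) and 3276 bp from Olfr972 (chromosome 9, 39877497 to 39877982, 12.8).

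The union of the lists held 112709 regions, of which 62204 were present in all 3 (55.2%), 12898 in Control only, 9711 in Mcrs1ox only and 8956 in the knockout only. A further 9024 were shared by Mcrs1ox and the knockout, 6818 by Control and the knockout, and 3098 by Control and Mcrs1ox. Of the 18735 regions gained in Mcrs1ox, 9711 were absent from the knockout (51.8%, interval 51.1 to 52.6), and of the 17980 regions gained in the knockout against Control, 8956 were absent from Mcrs1ox (49.8%, interval 49.1 to 50.5). Of the 19716 regions lost in Mcrs1ox, 6818 were present in the knockout (34.6%, interval 33.9 to 35.3), and of the 15996 regions lost in the knockout, 3098 were present in Mcrs1ox (19.4%, interval 18.76 to 19.99). For regions of matched strength that Mcrs1ox shared with Control, 9.62% were absent from the knockout, and for Control regions shared with Mcrs1ox 91.1% were present in it. These regions had already been called in 2 lists, so the matched shares are not an unbiased baseline.

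Among the 50505 regions present in 1 or 2 lists, Control was the list that differed from the other 2 in 21922 (43.4%, interval 43.0 to 43.8), Mcrs1ox in 16529 (32.7%, interval 32.3 to 33.1) and the knockout in 12054 (23.9%, interval 23.5 to 24.2). With only strong peaks the shares moved: of the 20000 strongest Mcrs1ox peaks 45 were missing from Control and the knockout held all 45, so 0 were absent after knockout, with an exact upper limit of 7.87%. Of the 20000 strongest Control peaks 178 were missing from Mcrs1ox, and the knockout held 108 of them (60.7%, interval 53.1 to 67.9).

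**Figure D3:**
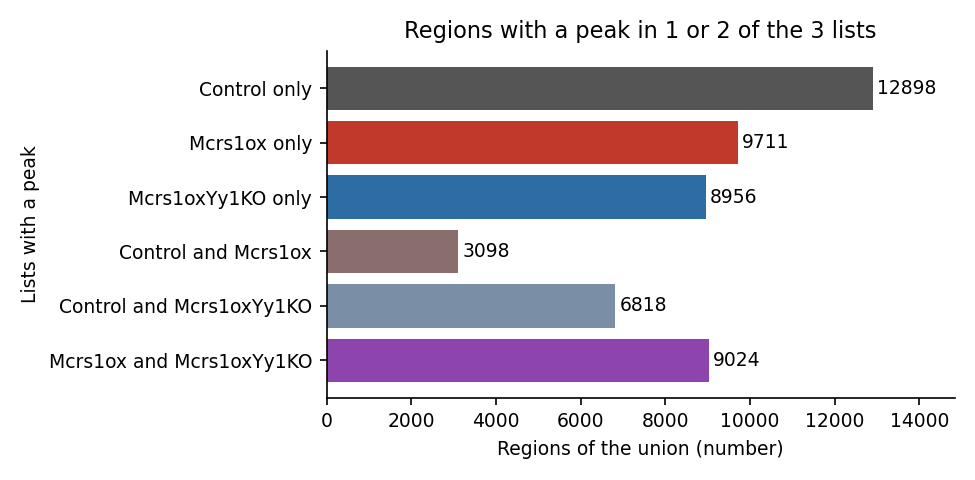
Number of union regions (x axis, from 0) by the lists that held a peak there (y axis), for regions with a peak in 1 or 2 of the 3 lists. The largest group was present in Control only (12898 regions) and the smallest was shared by Control and Mcrs1ox (3098).

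The comparison of the knockout with Control shared the Control list with the first comparison. Against Control, the knockout gained end peaks at Zfp114 (15.5), Gatm (14.1), Zfp612 (13.7), Zfp709 (13.2), the pair Rbak and Spdye4b (12.8), Zfp819 (12.7), Ccdc113 (12.2), Tmem200a (11.6) and Ccdc149 (11.5), all of which also had a Mcrs1ox peak. It lost end peaks at Dpys (17.6), a pyrimidine-degrading enzyme, at Map9, Hs3st3b1, Chst7 and Naa60. Further losses were at Fbxl21 (13.99), Itgb8 (13.8, an integrin), Rab38 (13.8) and Ahi1 (13.7). Of these genes Dpys kept a weak Mcrs1ox peak (5.21). Of the list members, Cd40, Tnf and Tie1 had an end peak in the knockout alone, and that of Tie1 overlapped a peak of each other list beyond 1 kb. Of 10 gained and 7 lost list members, Mycn alone kept its difference among the 30000 strongest peaks of each list. In total 462 genes gained an end peak and 411 lost it, or 434 and 383 without overlap beyond 1 kb. With each list cut to its 30000 strongest peaks they were 594 and 396, where the 594 include genes with an end peak in both full lists. With the 20000 strongest against full lists they were 16 and 21. The 16 include Bglap2, with an end peak that overlapped a Control peak beyond 1 kb.

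The strongest distal gains of the knockout over Control lay 21248 bp from Psme4 on chromosome 11 (30749990 to 30750527, 17.3) and 47070 bp from Clic5 on chromosome 17 (44327239 to 44327869, 16.6). Others lay inside Gas2 on chromosome 7 (51879065 to 51879735, 16.4) and Alox15 on chromosome 11 (70352845 to 70353530, 16.3), and 437165 bp from Serpinb8 on chromosome 1 (108046143 to 108046628, 15.9). The strongest losses lay inside Ank3 on chromosome 10 (69611721 to 69612343, 17.9) and 334790 bp from Nr2f2 on chromosome 7 (70016591 to 70017156, 17.1). Others lay 169266 bp from Cetn3 on chromosome 13 (81966421 to 81966997, 16.5), 173546 bp from Tmco5 on chromosome 2 (116704564 to 116705147, 16.4), and inside Acacb, a carboxylase of fatty acid metabolism, on chromosome 5 (114175532 to 114176125, 16.3). In all, 19613 knockout peaks overlapped no Control peak (20.7%, interval 20.4 to 21.0) and 16635 Control peaks overlapped no knockout peak (18.1%, interval 17.9 to 18.4). The genes of MHC class II and co-stimulation lay at percentile 99.8 (51 gained, 18 lost) at 92.3 with at most 1 member per 100 kb and at 16.0 among the 30000 strongest peaks of each list, and the other 14 lists lay between 2.9 (mesenchymal markers) and 97.3 (MHC class I, 55 gained, 21 lost).

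Gained and lost regions were spread unevenly over chromosomes. Of the regions that differed between Mcrs1ox and Control, 48.7% were gained over all chromosomes. The share was 31.4% on chromosome 18 (461 gained, 1005 lost, interval 29.1 to 33.9), 35.4% on chromosome 15 (623 gained, 1136 lost, interval 33.2 to 37.7), 39.9% on chromosome 3 and 40.2% on chromosome 13. On chromosome 11 it was 62.3% (1475 gained, 893 lost, interval 60.3 to 64.2). For the knockout against the same Control list the share was 52.9% over all chromosomes, 28.7% on chromosome 18, 34.2% on 15, 46.7% on 3, 45.4% on 13 and 68.2% on 11. Against Mcrs1ox it was 55.2% over all chromosomes and, in the same order, 51.0%, 51.6%, 60.0%, 58.4% and 55.5%. No 1 Mb window held 10 or more regions in 2 lists and 0 in the other. With at most 1 region in the other list, a limit chosen after seeing the data, 3 windows did, all short of Control peaks. They lay on chromosome 11 from 111000001, which holds Kcnj2 (1, 12 and 20 regions in Control, Mcrs1ox and the knockout), chromosome 14 from 9000001, which overlaps Fhit (1, 19 and 21), and chromosome 17 from 67000001, which overlaps Ptprm (1, 12 and 17).

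**Figure D4:**
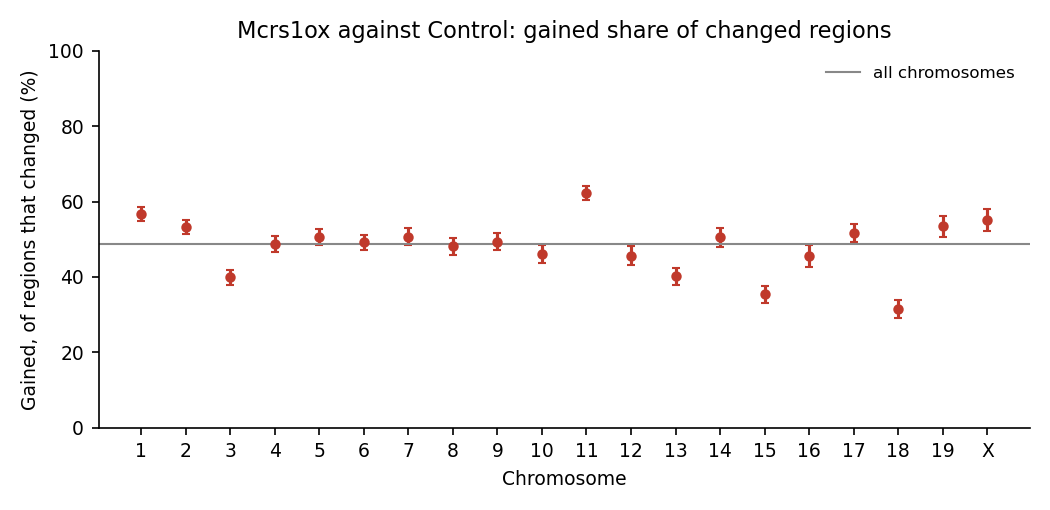
Percent of the regions differing between Mcrs1ox and Control that were gained (y axis, 0 to 100) for each chromosome except Y (x axis), with bars for the exact 95% binomial intervals of counting error and a line at the share over all chromosomes (48.7%). Chromosome 18 (31.4%) was lowest and chromosome 11 (62.3%) highest.

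The largest excess of Mcrs1ox regions lay on chromosome 6 from 18000001, a window that holds Cftr, the chloride channel of ductal epithelium, with 9 regions in Control, 49 in Mcrs1ox and 60 in the knockout. Windows with an excess in Control lay on chromosome 18 from 63000001 (55, 21 and 34 regions), which holds Piezo2, a mechanically gated channel, and on chromosome 15 from 54000001 (55, 25 and 33).

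**Figure D5:**
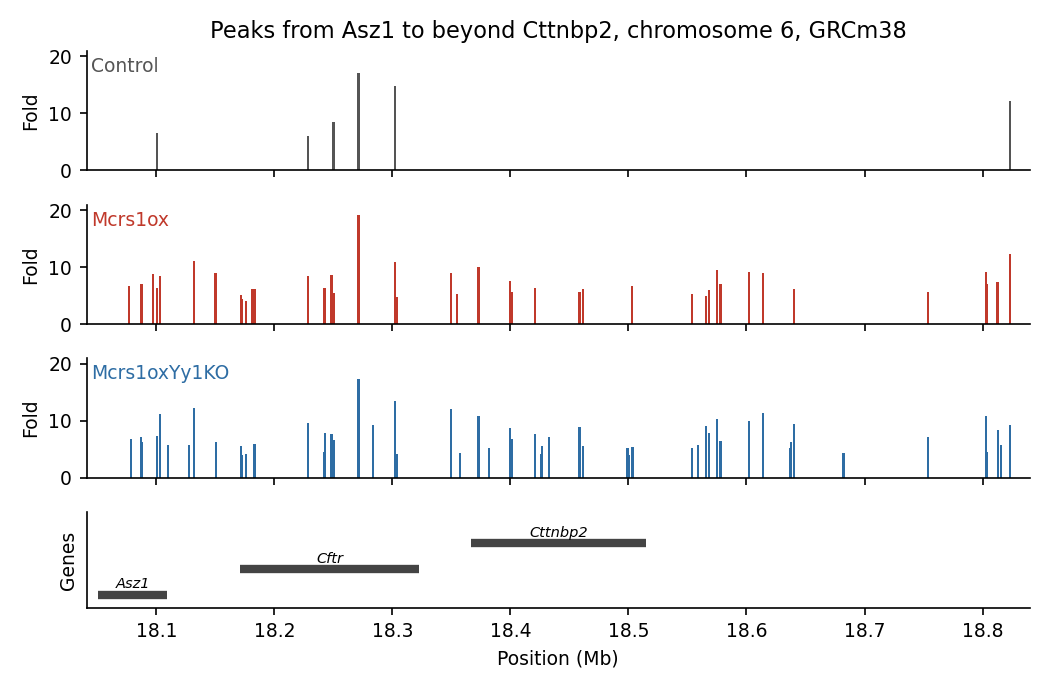
Peaks of each list from Asz1 to Cttnbp2 on chromosome 6 (x axis, position in Mb, GRCm38; y axis, fold enrichment of the peak in its own list, from 0), with protein-coding genes drawn to scale and narrow peaks drawn at a minimum width. Control had 7 peaks in this window, Mcrs1ox 44 and the knockout 58.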

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

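The alternatives with at most 1 list member per 100 kb, with no overlapping peak beyond 1 kb of a gene end, and all alternatives for the shares by chromosome were chosen after seeing the data. No paired analysis was possible because each condition has 1 list for both of its samples, and for the same reason no sample could be left out in turn. The alternatives for the YY1 motif and other motifs were not run for want of a genome sequence. Of 82 recomputed values that answer a comparison 38 stayed the same within their limits and 44 moved; the limits were 1.5 times for a count and the 95% binomial interval for a share, and none of these values had a called direction that could reverse. Counts of peaks per list stayed the same under each alternative run. With the 30000 strongest peaks of each list, 5415 peaks were gained and 5372 lost in Mcrs1ox, and 3561 gained and 3564 lost in the knockout against Mcrs1ox; these counts fall because fewer peaks enter. With presence among the 20000 strongest they were 45, 178, 0 and 0, and with 50% overlap 33896, 34586, 30004 and 26354. The share of gained regions absent after knockout was 54.3% at the shortest length, 47.4% with the 30000 strongest, 0% with the 20000 strongest (none of these Mcrs1ox peaks, gained or not, was missing from the knockout), 58.9% with 50% overlap and 49.9% by summit. The share of lost regions present after knockout was 31.85% at the shortest length, 60.7% with the 20000 strongest, 31.6% with 50% overlap and 36.3% by summit. Control was the list that differed in 44.6% at a −log10 q of 5, 44.3% at the shortest length, 47.0% with the 30000 strongest, 39.6% with 50% overlap and 100% of only 88 regions with the 20000 strongest, which left out 108 Control peaks missing from Mcrs1ox because the knockout held them as weaker peaks. The gene-end share of gained peaks was 17.4% with the 30000 strongest, 17.8% with the 20000 strongest, 10.9% with 50% overlap, 5.39% with 500 bp and 16.7% with 2500 bp; that of lost peaks was 7.41%, 11.2%, 10.0%, 4.25% and 12.2%. The MHC class I percentile for Mcrs1ox against Control was 99 at a −log10 q of 5, 98.1 at the shortest length, 93.3 with the 30000 strongest, 83.0 with 50% overlap, 97.4 by summit, 87.7 and 98.2 with links of 20 and 100 kb, and 79.0 with 1 member per 100 kb. With the 20000 strongest 40 of 45 percentiles, this one included, could not be given, since no changed region was left near the members. Where no construction is named, the cause was not tested. Of 1719 values for named genes and regions, gene lists and chromosomes, 1101 stayed the same, 613 moved and 5 reversed, that is, passed to the other side of 50 for a percentile outside the central 95% or passed the share over all chromosomes for a chromosome whose interval excluded it, a rule set after seeing the data. No chromosome share did. With the 30000 strongest, percentiles passed from 98.6 to 4.4 for endothelial markers and from 99.3 to 46.6 for the INO80 and NSL complexes (Mcrs1ox against Control), from 0.9 to 83.5 for ductal and from 2.4 to 69.4 for endothelial markers (knockout against Mcrs1ox), and from 99.8 to 16.0 for MHC class II and co-stimulation (knockout against Control). Of the 1719, 268 of 1030 moved for end peaks of named genes and 12 of 210 for named distal regions, and 0 of the 1030 changed direction. Of the gene-list percentiles 310 of 401 moved and 5 reversed, and of the chromosome shares 14 of 30 moved. Read depth limits which weak peaks were called and was unknown.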

Other observations

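Of the tests in this part, the rank shift by chromosome was fixed before its result was seen; the tests on parts of chromosomes, stretches without peaks, list lengths, strong peaks and zinc finger genes were chosen only after. Several neighbourhoods changed as a block. From Cftr, the chloride channel of ductal epithelium, to beyond Cttnbp2 on chromosome 6 (18303304 to 18815929) lay 34 consecutive regions, of which Control held 0, Mcrs1ox 22 and the knockout 33. A stretch that reached Onecut1, a transcription factor of pancreas development, held 17 regions on chromosome 9 (0 in Control, 12 in Mcrs1ox and 14 in the knockout). Another stretch, which overlapped antiviral genes of the Oas1 cluster on chromosome 5 (120820680 to 120907151), held 11 (0, 9 and 8). These counts are for the stretch and not for the whole cluster. Mcrs1ox held none of 22 regions around Adamts16 on chromosome 13 (22 in Control, 4 in the knockout), of 15 around Piezo2 on chromosome 18 (15 and 4), or of 10 around the receptor gene Fgfr2 on chromosome 7 (10 and 3). The knockout held none of 20 regions around Tenm4 on chromosome 7, where Control had 20 and Mcrs1ox 4.

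Among the 397 zinc finger genes with a Zfp symbol, examined because several led the gained end peaks, 13 gained an end peak in Mcrs1ox against Control that no Control peak touched, at percentile 93.8 of random lists whose central 95% ran from 3 to 14. Another 7 lost one, at percentile 20.6. An end peak was present at 306 of these genes in Control, 312 in Mcrs1ox and 311 in the knockout, so this family did not stand apart at the limits used. Outside the chromosomes kept there were 51 Control, 57 Mcrs1ox and 56 knockout peaks, and Fisher's exact test of their shares against Control gave p = 0.56 for Mcrs1ox and 0.77 for the knockout, a test that compares the lists and not the conditions.

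Stretches of 10 or more consecutive regions without a Control peak numbered 24, without a Mcrs1ox peak 46 and without a knockout peak 20. Independent dropout at an even rate over the genome is unlikely to account for the 24. In 1000 shuffles of presence among regions of the same strength decile there were at most 3. The shuffles held neither chromosome nor gene-end status, so they cannot decide on dropout at rates that differ from place to place. In the stretches without Control peaks the knockout held 282 of 338 regions and Mcrs1ox 221, and in those without Mcrs1ox peaks the knockout held 120 of 557. A change of whole domains with genotype may underlie these stretches, and so may a difference in copy number or between separately grown lines, neither of which was tested here.

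Chromosomes 15 and 18 lost more regions than they gained in Mcrs1ox, and chromosome 11 the reverse. More regions were lost than gained in 10 of 11 parts of 20 Mb of chromosomes 15 and 18, which argues against losses confined to a few domains. The count takes the sign of each part and not its size, so a few domains could still hold most of the excess. These chromosomes were picked for their losses, and over the genome lost regions also outnumbered gained ones (19716 and 18735). A chromosome-wide difference in copy number could not be settled: among gene-end regions shared by all lists, the median rank change by −log10 p was 0.04 on chromosomes 15 and 18 and 4.47 on chromosome 11, against a mean of 1.77 with SD 0.66 on the others. By fold enrichment it was 2.40 and 0.40 against 1.23 with SD 0.45, the opposite order, and the prediction had not said which measure would rank the peaks. By −log10 p the shift was lower on 15 and 18, and higher on 11, than on the other chromosomes. The prediction also called for a fall in rank from Control to Mcrs1ox on 15 and 18. With a median change of 0.04 no such fall was seen. Fold enrichment is a ratio to local background, which copy number could scale too, so that ranking is weak evidence against copy number. Copy number and other chromosome-wide differences therefore cannot be told apart from these lists, and genotype also stays open.

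The knockout list lay between the other lists for lost regions. Over all peaks different list lengths alone are unlikely to account for this. With each list cut to its 30000 strongest peaks, Control peaks missing from Mcrs1ox still outnumbered those missing from the knockout by 883 (8.9 counting SD). Both counts come from the same Control peaks and neighbouring peaks can be missing together, so this SD does not measure the spread between lists. At gene ends the order turned at that cut: 312 genes lost an end peak in Mcrs1ox and 396 in the knockout (496 and 411 with full lists). Chance placement of weak peaks stays open: the knockout held 60.67% of the 178 strong Control peaks missing from Mcrs1ox, and Mcrs1ox 12.5% of the 80 missing from the knockout, but the same 70 were missing from both, so the shares restate the pattern. A return of gained regions stays open too: 51.8% of all and 47.4% among the 30000 strongest peaks were absent after knockout, and at most 7.87% of the 45 among the 20000 strongest, where the knockout lacked no Mcrs1ox peak, gained or not. A partial return of lost regions with Yy1 targeting may be proposed as a hypothesis, and differences between cultures of 1 genotype could not be measured with 1 list per condition.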
